A study of Mus musculus with 12 samples.

How the data were processed

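Expression was measured in the adrenal medulla of 12 male mice on Affymetrix arrays, with 3 animals in each of 4 groups: colonized or germ-free, given saline or insulin. The deposited table holds log2 values made by the authors, and the submitters' processing notes name RMA (background correction, quantile normalization and summary per probe set) and limma, without versions. Whether all 12 arrays went through RMA together is not given in the sources used here. Values ran from 2.46 to 13.9, no columns were identical, and no values were transformed further.

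The table has 28846 rows. The annotation paired 19572 of them with 1 gene symbol, 0 with several and 9274 with none. The rows without a symbol comprise 5222 negative controls, 1324 positive controls, 63 ERCC spike rows, 23 background rows, 8 hybridization and poly-A controls and 2634 transcript rows, and these were not used in the comparisons. The Entrez identifiers of all 19572 rows were found in a gene table of assembly GRCm38.p6, which was used for names and genomic spans alone, and no symbol needed an update. A gene was counted once, by the probe set with the highest mean over the 12 arrays, giving 19505 genes, 55 of which had more than 1 probe set. The build behind the array annotation is not given in the sources used here, so no coordinates are reported.

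Group means and contrasts were fitted with limma 3.58.1 in R 4.3.3 on all 12 arrays (lmFit with 1 mean per group, eBayes without trend or robust options, 8 residual and 4.08 prior degrees of freedom). The 6 contrasts tested were the insulin effect in colonized and in germ-free mice, their difference, their mean, and germ-free minus colonized after saline and after insulin. P values were adjusted by the Benjamini-Hochberg method over 19572 probe sets and called at an adjusted p under 0.05, with no filter on dim values. All adjusted p values for genes are from limma, and errors beside fold changes are standard errors from that fit. The number of arrays limits the precision of all values.

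For gene lists, 540 symbols in 32 lists of pathways and cell types were fixed in advance and 483 of the listed genes were measured. Lists were tested with camera (preset correlation 0.01), which compares a list with all other genes, adjusted over the lists within a contrast. Camera with an estimated correlation and fry were run beside it; fry tests whether a list's genes move on balance one way and does not compare them with other genes. Camera with an estimated correlation called 3 lists for the insulin effect in colonized mice and 3 for the mean effect, namely immediate early genes, cyclic AMP targets and inflammation genes in both, and 0 for each of the other 4 contrasts, where the preset correlation called 12, 15, 8 and 13. Lists of intestine, pituitary, liver and sympathetic ganglion markers were written after the first results were seen and before the values of their members were looked up, and were used as scores and not in the list tests.

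The response score was the mean over the genes called for the mean insulin effect of the centred log2 value times the sign of that effect. Its difference between colonization states was tested with a two-sided exact permutation test of the colonization labels within each treatment (400 assignments), adjusted over 11 scores. Exchanging these labels assumes no effect of colonization of any kind. Where the level of a score differs between colonization states, its p need not hold for the difference of the insulin effects. It can then be too large.

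Genes were named by a rule: the 10 highest and 10 lowest changes among called genes whose groups did not overlap (for the mean effect, within both colonization states, and for the difference, called genes alone), up to 4 members with the largest change of each list described, and Th, Dbh, Pnmt, Ddc, Chga, Npy, Fos, Egr1 and Nr4a1 in every insulin contrast. Uninformative symbols, such as Gm followed by digits or ending in Rik, were counted but not named. Midn and the pituitary and intestine genes given by level were chosen after their values were seen. The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Covariates for adipocyte markers and for the negative controls, and the score over genes changed in both states, were added after the data were seen.

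Alternatives were all rows of the table, a filter on dim probe sets (mean under 6.85), 1 probe set per gene, a second quantile normalization, median centring, the trend and robust options, array weights, covariates for adrenal cortex, adipocyte and negative control levels, fits to the compared groups alone, 2 other thresholds, other gene sets for the score, and leaving out each array in turn. The pipeline was tested on simulated data with the same design. For the insulin effect in colonized mice over 19505 genes it called 89 of 100 simulated log2 changes of 1 and 99 of 100 changes of 2, with 3 false calls (1.57% of calls). For the mean effect over 19505 genes it called 99 of 100 and 100 of 100, with 7 false calls (3.40%). Of 32 simulated lists, 1 was called when 1 was shifted and 0 when none was. The permutation test gave p = 0.015 for a planted difference and p under 0.05 in 5.5% of 200 simulated sets without one. Those 200 sets held no difference of level between colonization states, so this share need not hold for scores with one. The simulated probe sets varied independently, without correlated genes, an outlying array or other tissue. The rates of false calls for genes and lists therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.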

Results

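Gene expression was measured with Affymetrix mouse arrays in the dissected adrenal medulla of 12 male C57Bl6 mice, 1 array per animal. Colonized mice carried a normal gut flora and germ-free mice carried none. After a fast of 3 h each animal received insulin (2 IU/kg, intraperitoneal) or saline, and the tissue was taken 90 min later. The 4 groups of 3 animals were colonized saline, colonized insulin, germ-free saline and germ-free insulin. Values were log2 RMA intensities for 28846 probe sets, of which 19572 were paired with 1 gene symbol (19505 genes). The number of arrays limits the precision of every value below. Arrays of one group correlated at r = 0.960 to 0.990 across probe sets, and at 0.985 or more once colonized saline animal 2 was left out. Colonized arrays correlated with germ-free arrays at a median r of 0.964.

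The pieces of tissue held transcripts of several cell types. The mean of 14 chromaffin markers (among them Th, Dbh and Pnmt, which make catecholamines) was 10.81 ± 0.27 (SD, n = 3) in colonized saline, 10.97 ± 0.24 in colonized insulin, 10.59 ± 0.07 in germ-free saline and 10.01 ± 0.24 in germ-free insulin mice. Adrenal cortex markers such as Cyp11a1 and Star averaged 11.63 ± 0.23, 11.97 ± 0.12, 12.09 ± 0.27 and 11.84 ± 0.02 in the same order. Adipocyte markers such as Ucp1 and Adipoq averaged 8.46 ± 1.99, 6.75 ± 1.13, 8.92 ± 0.40 and 9.99 ± 0.18, and ran from 6.26 to 10.13 among the 3 colonized saline arrays. Liver markers averaged 7.35 ± 2.17, 5.66 ± 0.04, 8.01 ± 0.82 and 6.69 ± 0.87. Markers of intestinal epithelium averaged 5.18 ± 0.09, 5.22 ± 0.03, 5.96 ± 0.50 and 5.21 ± 0.08. Sustentacular and Schwann cell markers averaged 7.59 ± 0.50, 7.13 ± 0.18, 6.74 ± 0.05 and 7.01 ± 0.08.

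**Figure D1:**
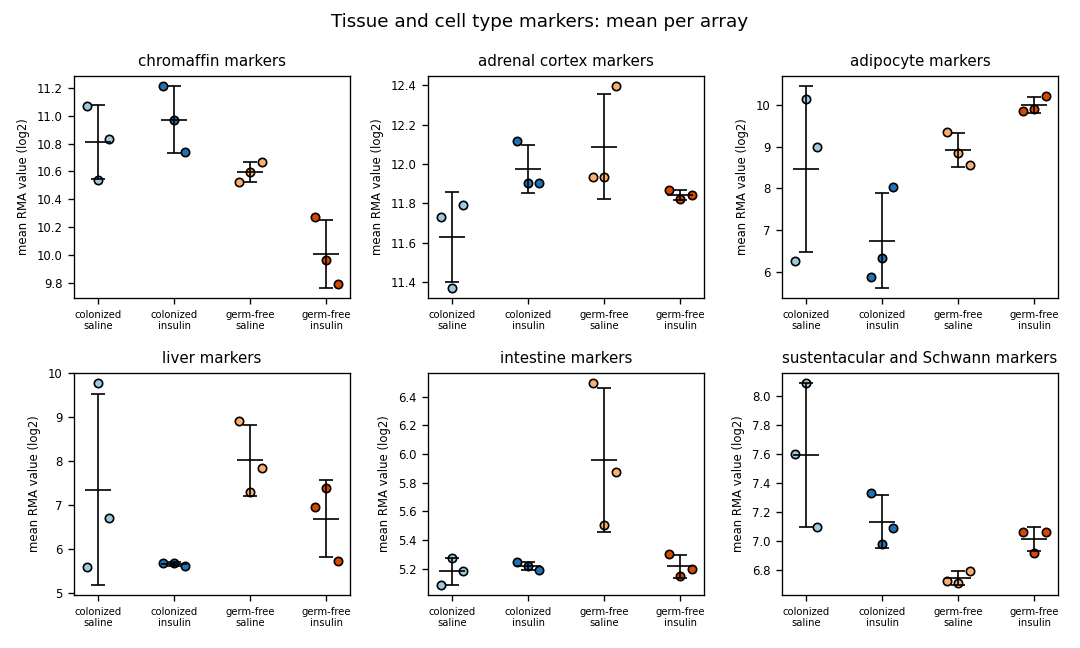
Mean log2 RMA value of the markers of 6 tissues or cell types in each array (points), with the group mean and SD (bars, n = 3 arrays per group). Adipocyte markers ranged from 6.26 to 10.13 within the colonized saline group, and intestine markers reached 6.49 in 1 germ-free saline array.

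The first comparison asked which genes of the colonized adrenal medulla differed between insulin and saline. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose most, by 3.78 ± 0.46 on the log2 scale (SE, n = 3 arrays per group, limma adjusted p = 0.0189; probe set mean 5.16 after saline and 8.94 after insulin). Tac1, the precursor of substance P, rose by 2.43 ± 0.41 (adjusted p = 0.0463), and Vgf, a neuropeptide precursor of secretory granules, by 1.79 ± 0.28 (adjusted p = 0.0429). The immediate early transcription factor genes Nr4a2 (2.12 ± 0.36), Fosb (1.26 ± 0.17) and Egr1 (1.20 ± 0.19) rose as well. Txnip and Arrdc4, arrestin family genes that restrain glucose uptake, fell by 1.17 ± 0.16 and 0.81 ± 0.13. Angptl4, an inhibitor of lipoprotein lipase, fell by 1.41 ± 0.19, and Adm, which encodes the vasodilator adrenomedullin, by 1.31 ± 0.21.

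In all, 29 genes were called for insulin in colonized mice, 21 higher and 8 lower, and 2294 genes had an unadjusted p under 0.05. The others among the 10 highest were Prl8a2 (2.35), Tent5a (1.58), Csrnp1 (1.46), Tmcc3 (1.42), Dusp8 (1.42) and Mycn (1.37), and the remaining lower genes were Parp16 (-1.07), Ucp3 (-0.94), Ypel2 (-0.82) and Zfyve1 (-0.57). The 3 insulin arrays lay on one side of the 3 saline arrays for 14.1% of all genes, against 10% given by chance, and for each called gene named, as the naming rule required of those of largest change. The genes of catecholamine synthesis were not called: Th changed by 0.38 ± 0.16, Dbh by 0.29 ± 0.19, Pnmt by 0.51 ± 0.27 and Ddc by 0.0092 ± 0.18, a value whose sign flipped with a second quantile normalization. Th was the highest probe set of colonized insulin arrays 4 and 5 (13.91 and 13.87) and Dbh and Chga reached 13.65 and 13.55 there, so near the top of the scale their changes are not exact. Chga (0.38), Npy (0.58) and Fos (0.59) were not called either, and Nr4a1 (1.17 ± 0.21) had an adjusted p of 0.0525. For the colonized insulin effect limma called 0 genes with the compared groups alone, with the adrenal cortex covariate and with the adipocyte covariate, the last chosen after the data were seen (1373, 1168 and 1616 at an unadjusted p under 0.05). Leaving out single arrays gave 1 to 70 genes. Of these 12 fits Tent5a kept its call in 12, Ptgs2 in 8, Txnip and Angptl4 in 6, Adm in 3, Nr4a2, Vgf, Egr1 and Arrdc4 in 2 and Tac1 in 1.

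Among the gene lists, the 28 immediate early genes in colonized mice had a median of 0.65 and 28 of 28 members above 0 (camera adjusted p = 2.16e-21). Of these members 3 were called over all genes and 19 when adjusted over the list alone. Targets of cyclic AMP and CREB had a median of 0.35 with 2 members called (7 adjusted over the list alone), and inflammation genes a median of 0.24 with 1 called (6 adjusted over the list alone). These 3 lists were also called with an estimated correlation, at adjusted p of 0.0111, 0.0421 and 0.0421. Cholesterol synthesis genes had a median of 0.45 with 16 of 16 members above 0 and no member called (6 adjusted over the list alone), adjusted p = 0.462 with an estimated correlation. The FOXO and insulin pathway list, with Txnip and Fbxo32 (-0.98, not called) at its lower end, had a median of -0.27 and 2 members called lower (4 higher and 8 lower adjusted over the list alone), adjusted p = 0.462 with an estimated correlation. Camera also called neuropeptides and granins (median 0.17), steroid synthesis (0.13), adrenal cortex markers (0.29), respiratory chain subunits (-0.18), Schwann cell markers (-0.47), fibroblast markers (-0.81) and adipocyte markers (-1.77), each with an adjusted p = 0.462 with an estimated correlation. Interferon genes (median 0.13) were the remaining called list, adjusted p = 0.522 with an estimated correlation. Adjusted over the list alone, 5 neuropeptide genes, 1 steroid synthesis gene, 1 interferon gene, 1 Schwann cell gene and 4 adipocyte genes were called, beside 3 neuropeptide genes and none of the others over all genes. Without colonized saline animal 2, adjusted p was 0.111 for neuropeptides and for interferon genes, 0.122 for steroid synthesis, 0.130 for cortex markers and 0.107 for respiratory chain subunits. It was 0.057 for Schwann cell markers, 0.629 for fibroblast markers and 0.135 for the FOXO list, none of them called. Fibroblast markers reversed with the adipocyte covariate (adjusted p = 0.293).

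**Figure D2:**
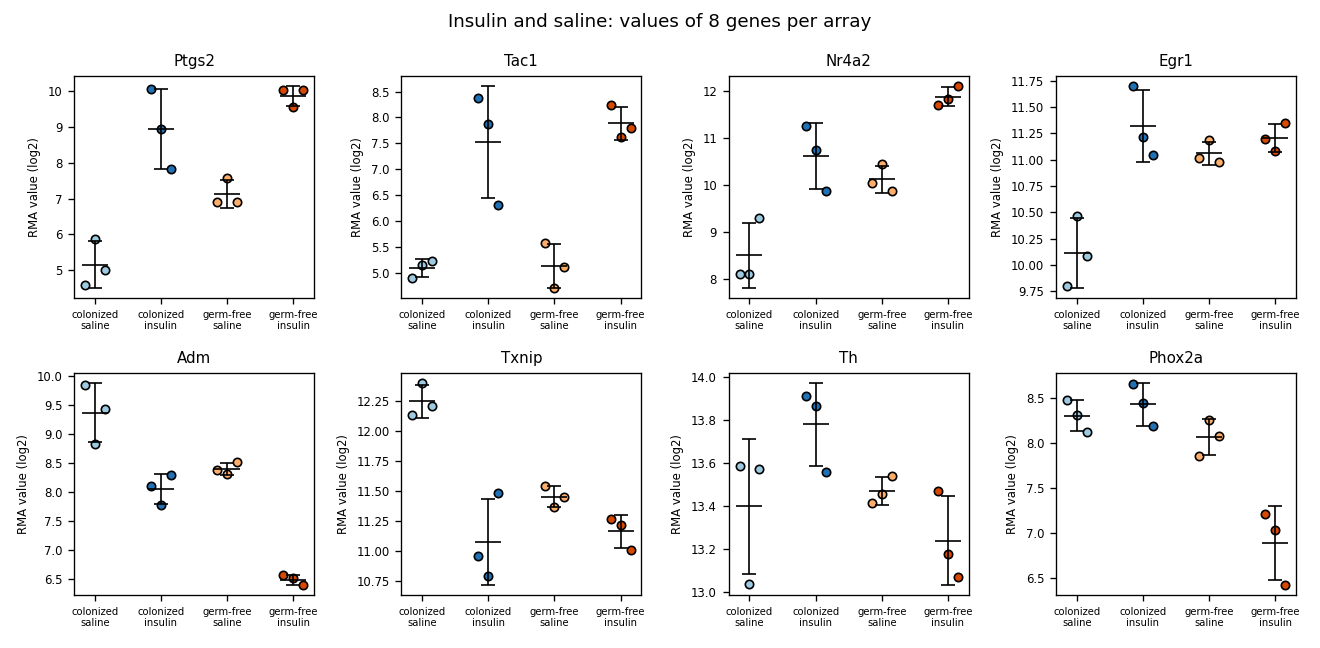
Log2 RMA values of 8 genes in each array (points) with the group mean and SD (bars, n = 3 arrays per group). Ptgs2 and Tac1 were higher in every insulin array than in every saline array of the same colonization state, and Adm was lower. Th moved by 0.38 in colonized and -0.23 in germ-free mice and was not called.

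In germ-free mice insulin raised Ptgs2 by 2.73 ± 0.46 (limma adjusted p = 0.0232, n = 3 arrays per group), Tac1 by 2.75 ± 0.41 (adjusted p = 0.0122) and Fosb by 0.99 ± 0.17, and lowered Adm by 1.90 ± 0.21. The pituitary hormone genes Gh (4.48 ± 0.44), Prl (3.08 ± 0.40), Cga (2.08 ± 0.30) and Pomc (1.66 ± 0.21) rose, as did Ptgds (3.86 ± 0.47), which encodes prostaglandin D synthase. Genes of intestinal epithelium were the lowest: Reg1 fell by 5.43 ± 0.37, Guca2b by 4.45 ± 0.40, Akp3 by 4.06 ± 0.46, Fabp2 by 3.86 ± 0.44 and Alpi by 3.60 ± 0.39. These genes lay in germ-free insulin arrays near their colonized level (Reg1 at 3.75 against 3.69 in colonized saline arrays) and stood out in the germ-free saline arrays (9.17). Other tissue in the samples, left open below, may contribute to the changes of the intestinal and of the pituitary hormone genes. Reg1, Akp3, Fabp2, Muc13, Pigr, Gsta2 and Cdh17 after insulin, and Tac1, Cga and Pomc after saline, lay below the negative controls of their arrays (5.42 and 5.41), so their fold changes are not exact. The transcription factor genes Gata2, Phox2a and Hand2 of the chromaffin lineage fell by 1.26 ± 0.18 (adjusted p = 0.0101), 1.18 ± 0.20 and 0.89 ± 0.16.

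The comparison called 85 genes in germ-free mice, 27 higher and 58 lower, and 1617 had an unadjusted p under 0.05. Ppp1r3b (1.95), Dio2 (1.91) and Tmcc3 (1.64) completed the 10 highest, and Pigr (-3.94), Muc13 (-3.91), Gsta2 (-3.55), Apoa4 (-3.42) and Cdh17 (-3.08) the 10 lowest. The groups did not overlap for 19.7% of all genes (10% by chance), nor for the called genes named, as the naming rule required of those of largest change. Not called were Th (-0.23 ± 0.16), Dbh (-0.58 ± 0.19), Pnmt (-0.74 ± 0.27), Ddc (-0.53 ± 0.18), Chga (-0.44 ± 0.18), Npy (-0.10 ± 0.25), Fos (-0.06 ± 0.26), Egr1 (0.15 ± 0.19) and Nr4a1 (0.41 ± 0.21). Leaving out single arrays gave 25 to 199 called genes. Of these 12 fits Gh, Prl, Pomc, Reg1 and Guca2b kept their call in 12, Cga in 10, Tac1 in 9, Ptgs2 in 7, Pigr in 5 and Dio2 in 4.

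Chromaffin markers had a median of -0.53 after insulin in germ-free mice, with 13 of 14 members below 0, 3 called and 10 adjusted over the list alone (camera adjusted p = 1.24e-12, adjusted p = 0.126 with an estimated correlation). The catecholamine list (median -0.31) had no member called by either adjustment, adjusted p = 0.213 with an estimated correlation. Receptors and channels for the splanchnic input (-0.25) had 1 member called, the sodium channel gene Scn3a (-1.06 ± 0.18), and 3 adjusted over the list alone. Immediate early genes (0.39, 24 of 28 above 0), cyclic AMP targets (0.40) and inflammation genes (0.18) were called upward, with 1, 2 and 1 members called and 11, 8 and 4 adjusted over the list alone. These 3 lists and the receptor list had an adjusted p = 0.0634 with an estimated correlation. Respiratory chain subunits (0.27, 22 of 22 above 0) had no member called by either adjustment, adjusted p = 0.104 with an estimated correlation. Glycolysis genes had a median of 0.09, with Hk2 called (0.89 ± 0.16) and 2 adjusted over the list alone, adjusted p = 0.124 with an estimated correlation. Interferon genes (-0.25, 22 of 23 below 0, 4 adjusted over the list alone) and antigen presentation genes (-0.34, 14 of 14 below 0, none adjusted over the list alone) had an adjusted p = 0.153 with an estimated correlation. Exocytosis genes (-0.14) had an adjusted p = 0.329 with an estimated correlation, and adipocyte markers (0.83, 2 adjusted over the list alone) an adjusted p = 0.475 with an estimated correlation.

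**Figure D3:**
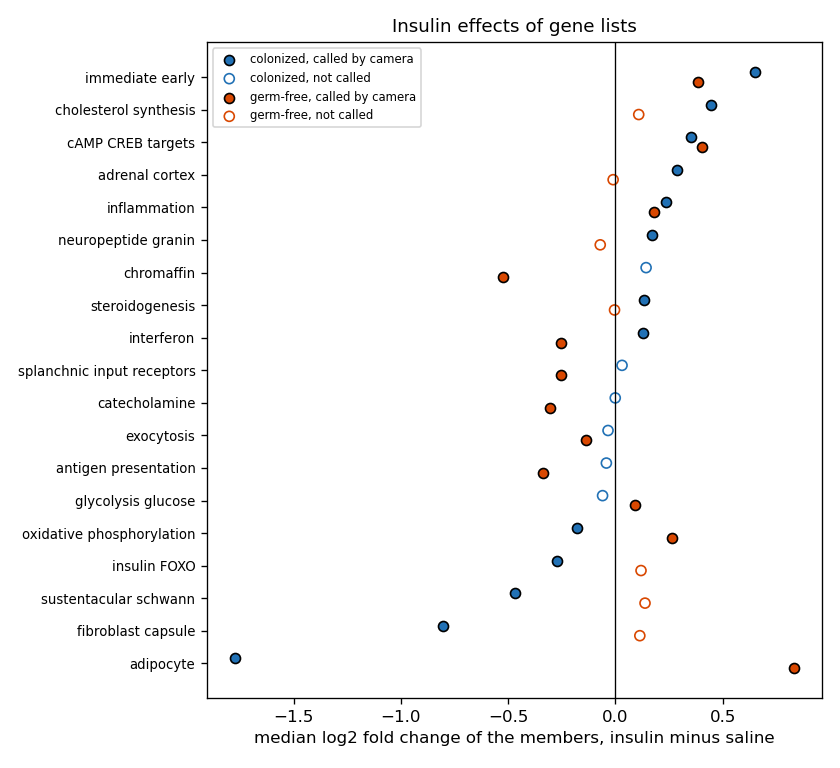
Median log2 fold change after insulin of each gene list that camera called in either colonization state (filled points called, open points not called; n = 3 arrays per group). Immediate early genes lay above 0 in both states (0.65 and 0.39), and chromaffin markers lay at 0.14 in colonized and -0.53 in germ-free mice.

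The study's central comparison asked whether the insulin effect differed between germ-free and colonized mice, and the difference itself was tested. Growth hormone (Gh) had a more positive insulin effect in germ-free mice, by 4.32 ± 0.63 (limma adjusted p = 0.0462, n = 3 arrays in each of 4 groups), as did Slc25a20, the mitochondrial carnitine carrier, by 1.06 ± 0.15. The intestinal genes Reg1 (-5.43 ± 0.53), Guca2b (-4.52 ± 0.57), Muc13 (-3.83 ± 0.53) and Slc5a1 (-3.20 ± 0.46) and the RNA editing gene Adarb1 (-1.52 ± 0.22) had a more negative one. Reg1, Muc13 and Slc5a1 lay below the negative controls in colonized saline and germ-free insulin arrays, so their differences are not exact. Reg1 stood out in the germ-free saline arrays alone (8.33 to 10.37, against 3.54 to 3.93 in all other arrays). Other tissue in the samples, left open below, may contribute to the differences of the intestinal genes and of Gh beside the state of the gland. These 7 genes were all that were called, while 1941 had an unadjusted p under 0.05. For the catecholamine genes the difference was -0.61 ± 0.23 for Th (adjusted p = 0.402), -0.86 ± 0.27 for Dbh, -1.25 ± 0.39 for Pnmt and -0.54 ± 0.26 for Ddc, none of them called, with Th and Dbh near the top of the scale, where changes are not exact. Chga (-0.82), Npy (-0.68), Fos (-0.65), Egr1 (-1.06, adjusted p = 0.212) and Nr4a1 (-0.76) were not called. Leaving out single arrays gave 1 to 83 genes, with Reg1 called in 12 of the 12 fits, Guca2b and Slc5a1 in 5, Gh, Muc13 and Adarb1 in 4 and Slc25a20 in 3. For the difference limma called 0 genes with dim probe sets left out and with the adrenal cortex or adipocyte covariate (1210, 958 and 1365 at an unadjusted p under 0.05).

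Camera called 15 lists for the difference, none of them with an estimated correlation. Chromaffin markers had a median of -0.73 for it, with 13 of 14 members below 0 and 10 lower adjusted over the list alone against none over all genes, adjusted p = 0.237 with an estimated correlation. Receptors (-0.22, 3 lower adjusted over the list alone), immediate early genes (-0.30, 2 lower adjusted over the list alone), interferon genes (-0.41, 3 lower), the FOXO list (0.25, 7 higher) and respiratory chain subunits (0.43, 22 of 22 above 0, 2 higher) also had an adjusted p = 0.237 with an estimated correlation. Adipocyte markers (2.55, 7 higher adjusted over the list alone) and Schwann cell markers (0.41, 1 higher) had an adjusted p = 0.267 with an estimated correlation, and glycolysis genes (0.26, 1 lower adjusted over the list alone) one of 0.256. The catecholamine list (-0.46), cholesterol synthesis (-0.34), antigen presentation (-0.19) and fibroblast markers (0.88) had an adjusted p = 0.482 with an estimated correlation, and neuropeptides (-0.30) and adrenal cortex markers (-0.29) one of 0.404. With the adrenal cortex and adipocyte covariates cholesterol synthesis (adjusted p = 0.307 and 0.512) and fibroblast markers (0.257 and 0.000993) turned to the opposite direction. No member of these 15 lists was called over all genes.

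The size of the response was compared on 1 score per array, built from the 80 genes called for the mean of both insulin effects. The score rose by 0.77 in colonized and by 1.41 in germ-free mice, a difference of 0.64 (exact permutation p = 0.01, and 0.11 adjusted over 11 scores). The genes were called with the spread within the real groups, and the permutations did not repeat that choice. The p of this score is therefore approximate. Of the 80 genes 41 had the larger effect in colonized and 39 in germ-free mice, with median sizes of 0.72 and 0.96. The difference was 0.035 (exact permutation p = 0.905) with dim probe sets left out and -0.011 (exact permutation p = 0.97) without colonized saline animal 1. Among the 80 genes, 49 had an unadjusted p under 0.05 in the same direction in each state, such as Ptgs2, Tac1, Nr4a2 and Adm. Over these 49 the score rose by 1.01 in colonized and 0.87 in germ-free mice, which was not tested. The larger rise in germ-free mice over all 80 therefore came from the other genes, which include Lypd8 and Cyp3a13. Whether other tissue in the samples, left open below, contributes to the changes of these other genes was not tested. Immediate early genes rose on average by 0.69 in colonized and 0.38 in germ-free mice (exact permutation p = 0.25, 0.594 adjusted), and chromaffin markers moved by 0.16 and -0.59 (exact permutation p = 0.14, 0.594 adjusted). The permutations assume no effect of colonization of any kind. Immediate early scores already differed after saline (8.19 to 8.26 in colonized and 8.68 to 8.79 in germ-free arrays). Such p values can be too large and do not show that the effects were alike. Across all genes the insulin effects of the 2 states, which share no array, correlated at r = 0.107 and rho = -0.0078, with 49.7% of genes of the same sign. Across the 80 genes r was 0.532 and rho 0.652, with 93.8% of the same sign. These genes were chosen for the mean of both effects, which favours one sign in both states. Of the 29 genes called in colonized mice 28 had the same sign in germ-free mice and 16 an unadjusted p under 0.05 there. Of the 85 genes called in germ-free mice 46 had the same sign in colonized mice and 16 an unadjusted p under 0.05. Genes called higher in both states were Fosb, Mest, Midn, Ptgs2, Tac1 and Tmcc3 (6 against 0.0291 expected by chance), and Adm was the 1 gene called lower in both (0.0238 expected).

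**Figure D4:**
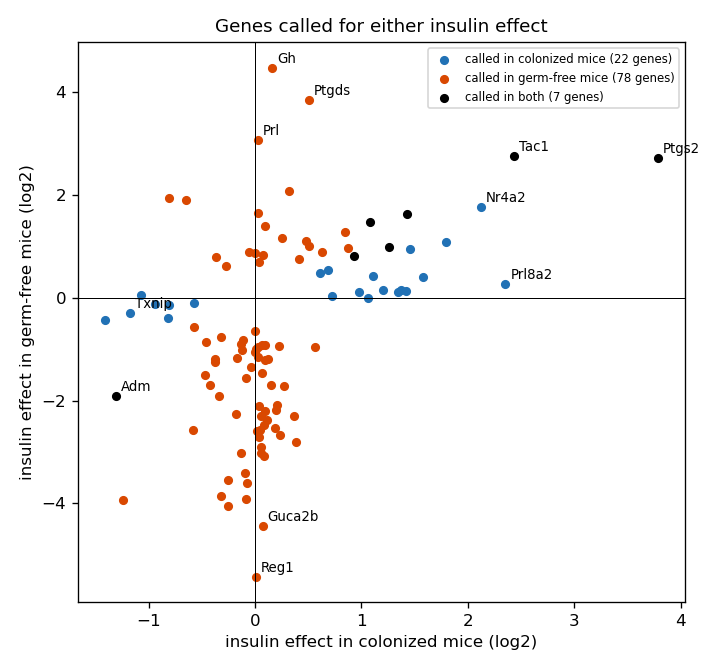
Log2 fold change after insulin in colonized mice (x axis) and germ-free mice (y axis) of each gene called in at least 1 of the states (n = 3 arrays per group). The 7 genes called in both, such as Ptgs2 and Tac1, lay off both axes, and the intestinal genes Reg1 and Guca2b lay near 0 in colonized mice.

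Averaged over both colonization states, insulin raised Ptgs2 by 3.26 ± 0.33 (limma adjusted p = 0.00176, n = 6 arrays per treatment), Tac1 by 2.59 ± 0.29, Nr4a2 by 1.94 ± 0.25 and Vgf by 1.44 ± 0.20. Sik1, a kinase gene induced by cyclic AMP, rose by 1.24 ± 0.19, and Nr4a1 by 0.79 ± 0.15 (adjusted p = 0.0471). Adm (-1.60 ± 0.15), Angptl4 (-0.91 ± 0.13) and Txnip (-0.73 ± 0.11) fell. A total of 80 genes were called, 48 higher and 32 lower, 2014 had an unadjusted p under 0.05, and single arrays left out gave 26 to 131 genes. The other named genes were Tmcc3 (1.53), C2cd4b (1.32), Mest (1.28), Csrnp1 (1.21) and Fosb (1.13), with Cyp3a13 (-1.58), Lypd8 (-1.57), Gvin1 (-0.66), Trim21 (-0.65), Ypel2 (-0.60), Rsrp1 (-0.57) and Zfp60 (-0.54). Egr1 (0.68 ± 0.13, adjusted p = 0.0546), Th (0.08 ± 0.12), Dbh (-0.14), Pnmt (-0.11), Ddc (-0.26), Chga (-0.031), Npy (0.24) and Fos (0.26) were not called.

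Immediate early genes (median 0.55, 27 of 28 above 0, 7 called, 22 adjusted over the list alone), cyclic AMP targets (0.25, 6 called, 11 adjusted over the list alone) and inflammation genes (0.19, 2 called, 7 adjusted over the list alone) were called for the mean insulin effect. They were also called with an estimated correlation, at adjusted p of 0.00713, 0.0158 and 0.0146. Chromaffin markers (-0.15, with Gata2 called at -0.82 ± 0.13 and 3 adjusted over the list alone), the catecholamine list (-0.14), cholesterol synthesis (0.26, 16 of 16 above 0) and macrophage markers (-0.16, 1 higher and 1 lower adjusted over the list alone) were called, adjusted p = 0.458 with an estimated correlation. Steroid synthesis (0.076), with Nr4a1 called, had an adjusted p = 0.458 with an estimated correlation as well. Heat shock genes (-0.10) had an adjusted p = 0.556 with an estimated correlation, and antigen presentation genes (-0.20, 13 of 14 below 0, 4 adjusted over the list alone) one of 0.386. With single arrays left out macrophage markers were called in 5 of 12 fits, heat shock and steroid synthesis genes in 7 and the catecholamine list in 8.

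After saline, germ-free and colonized mice were compared without insulin. Other tissue in the samples and an array batch, both left open below, may contribute to this difference beside the state of the gland. Genes of intestinal epithelium were the highest in germ-free mice: the lectin gene Reg1 at 5.49 ± 0.37 (limma adjusted p = 3.54e-05, n = 3 arrays per group), Guca2b at 4.67 ± 0.40, Akp3 at 4.39 ± 0.46, Muc13 at 4.07 ± 0.37 and Alpi at 3.74 ± 0.39. Of the immediate early genes 10 of 28 were called higher, such as Ier3 at 1.95 ± 0.26, Nr4a2 at 1.62 ± 0.36 and Nr4a1 at 1.19 ± 0.21. Of the cyclic AMP targets 8 of 20 were called higher, such as Ptgs2 (1.97 ± 0.46), Gem (1.85 ± 0.28) and Pde10a (1.85 ± 0.18). Both lists had an adjusted p = 0.0951 with an estimated correlation. Nr5a1, the transcription factor of steroid-producing cells, was higher by 0.72 ± 0.14. Fabp7 (-2.66 ± 0.62) and Mbp (-1.27 ± 0.31), of the Schwann cell list (3 of 9 members called, adjusted p = 0.437 with an estimated correlation), were lower. The connexin gene Gjc3 (-1.63 ± 0.39) and the neuronal calcium sensor gene Hpca (-1.83 ± 0.21) were lower as well. Sympathetic ganglion markers also averaged lower in germ-free saline (7.88) than in colonized saline arrays (8.62). Colonized saline animal 2 had the highest Schwann cell (8.09) and ganglion (9.48) scores of all arrays. Reg1, Akp3, Muc13, Gsta2 and Slc5a1 lay below the negative controls (4.75) in the colonized saline arrays, so their differences are not exact. The colonized saline arrays also serve as the baseline of the insulin effect in colonized mice, so these comparisons are not independent.

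A total of 1342 genes were called after saline, 544 higher and 798 lower, 195 of them at least 2-fold, and 4687 had an unadjusted p under 0.05. The count was 432 to 1929 with single arrays left out. Of these 12 fits Reg1 and Hpca kept their call in 12, Gjc3 in 9, Fabp7 in 8 and Sult4a1 in 6, with values down to -1.07, -1.72 and -1.15 for the last 3. The count was 157 with the compared groups alone (94 higher and 63 lower). It was 0 by limma with a negative control covariate chosen after the data were seen (968 at an unadjusted p under 0.05). The negative controls were 0.50 higher in germ-free arrays. Fabp2 (3.45), Gsta2 (3.39), Apoa4 (3.38), Slc5a1 (3.23) and Mgam (3.14) completed the 10 highest, and Sult4a1 (-1.91), Susd3 (-1.68), Hhex (-1.66), Gpnmb (-1.66), Rab15 (-1.59), Sfrp1 (-1.57) and Mmd2 (-1.47) the 10 lowest. Groups did not overlap for 27.3% of genes (10% by chance), nor for the called genes named, as the naming rule required of those of largest change. Of the called genes 40.5% were higher, against 27.2% after a second quantile normalization and 8.70% after median centring, which moved the median of all genes from -0.040 to -0.11 and -0.21. Immediate early genes had a median of 0.41 with 10 called (12 adjusted over the list alone) and cyclic AMP targets one of 0.41 with 8 called higher and 1 lower (10 and 1 adjusted over the list alone), both with adjusted p = 0.0951 with an estimated correlation. Steroid synthesis genes had a median of 0.35 with 2 called (3 adjusted over the list alone), adjusted p = 0.355 with an estimated correlation. Adrenal cortex markers (0.35, 1 called, 2 adjusted over the list alone) had an adjusted p = 0.454 with an estimated correlation, and Schwann cell markers (-0.73, 3 called, 6 adjusted over the list alone) one of 0.437. The catecholamine list (-0.41, none called, 9 lower adjusted over the list alone), cholesterol synthesis (-0.41, 6 called by either adjustment, such as Fdps at -0.88 and Mvd at -0.83) and respiratory chain subunits (-0.19, 1 called, 1 higher and 2 lower adjusted over the list alone) had an adjusted p = 0.604 with an estimated correlation. After median centring the medians were 0.24 for immediate early genes and for cyclic AMP targets, 0.18 for steroid synthesis and for cortex markers and -0.36 for respiratory chain subunits, which reversed with the adrenal cortex covariate (adjusted p = 0.792). Lists of microbial sensors (median -0.20, camera adjusted p = 0.433) and of receptors for microbial metabolites (camera adjusted p = 0.922) were not called, while Lbp (-0.79 ± 0.18) and Cyp1b1 (-1.09 ± 0.20) in them were.

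After insulin, the brown fat genes Ucp1 (6.84 ± 1.33, limma adjusted p = 0.011, n = 3 arrays per group), Elovl3 (4.07 ± 0.69), Cidea (3.51 ± 0.79) and Ppargc1a (3.43 ± 0.58) were higher in germ-free than in colonized mice. Gh (5.55 ± 0.44), Prl (3.37 ± 0.40), Ptgds (3.47 ± 0.47) and Ttr (4.44 ± 1.00) were higher too. Of 14 chromaffin markers 10 and of 16 catecholamine genes 7 were called lower (both lists adjusted p = 0.238 with an estimated correlation), among them Phox2a at -1.55 ± 0.20 (adjusted p = 0.00266), Pnmt at -1.22 ± 0.27 (adjusted p = 0.0202), Cyb561 at -1.20 ± 0.20 and Pcbd1 at -1.18 ± 0.22. The transcription factor gene Tfap2b was lower at -1.69 ± 0.18. Snap25, of the exocytosis list (6 of 21 members called, adjusted p = 0.282 with an estimated correlation), was lower at -1.60 ± 0.24. Scg3 (-1.39 ± 0.23) and Pcsk1n (-1.33 ± 0.24), of the neuropeptide and granin list (6 of 22 members called, adjusted p = 0.308 with an estimated correlation), were lower too. Of 18 genes of receptors and channels for the splanchnic input, 6 were called lower and 2 higher (adjusted p = 0.238 with an estimated correlation). The lower ones included the PACAP receptor gene Adcyap1r1 at -1.59 ± 0.26 and the nicotinic subunit genes Chrnb4 at -1.29 ± 0.34, Chrna7 at -1.26 ± 0.27 and Chrnb2 at -1.23 ± 0.16. The mean of the adipocyte markers was 9.99 in these germ-free arrays and 6.75 in the colonized insulin arrays, where Ucp1 (4.72) and Elovl3 (3.97) lay below the negative controls (4.75), so their differences are not exact. Uneven fat or other tissue and an array batch, left open here, may contribute to this comparison beside the state of the gland. That holds for the lower chromaffin, receptor and exocytosis genes as well.

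This comparison called 1512 genes, 507 higher and 1005 lower, 359 of them at least 2-fold, and 4379 had an unadjusted p under 0.05. The count was 450 to 2841 with single arrays left out and 0 by limma with the negative control covariate (900 at an unadjusted p under 0.05). Of the 12 fits Ucp1 kept its call in 11, Ttr in 8, Cidea in 7 and Cdo1 and Adtrp in 3. Cdo1 (3.65) and Adtrp (3.54) completed the 10 highest, and Rtl4 (-2.17), Slc7a14 (-2.05), Mab21l2 (-1.92), Rab15 (-1.88), Nrsn2 (-1.87), Prl8a2 (-1.87), Tbx20 (-1.82), Cd55 (-1.67) and Hpca (-1.67) the 10 lowest. Groups did not overlap for 31.9% of genes (10% by chance), nor for the called genes named, as the naming rule required of those of largest change. Of the called genes 33.5% were higher, against 9.60% after median centring, which moved the median of all genes from -0.032 to -0.19 (-0.11 after a second quantile normalization). With the adipocyte score as a covariate, an alternative chosen after the data were seen, 42 genes were called, 21 of them among the 1512. That score ran from 5.88 to 8.03 in colonized insulin and from 9.86 to 10.20 in germ-free insulin arrays. Fat and colonization are therefore hard to tell apart here. The differences after saline and after insulin, which share no array, had 159 higher genes (14.1 expected by chance) and 322 lower genes (41.1 expected) in common and correlated across genes at r = 0.450 and rho = 0.454.

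Chromaffin markers were lower in germ-free mice after insulin, with a median of -1.04, 14 of 14 below 0, 10 called and 13 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation. The catecholamine list (-0.64, 7 called, 9 adjusted over the list alone) and the receptor list (-0.44, 6 called lower and 2 higher, 8 and 2 adjusted over the list alone) also had an adjusted p = 0.238 with an estimated correlation. Cyclic AMP targets (0.43, 7 called, 7 higher and 2 lower adjusted over the list alone) and kidney and liver genes (0.14, Ttr called by either adjustment) shared that value. Neuropeptides and granins (-0.47, 6 called, 1 higher and 10 lower adjusted over the list alone) had an adjusted p = 0.308 with an estimated correlation. Exocytosis genes (-0.31, 6 called, 1 higher and 10 lower adjusted over the list alone) and cholesterol synthesis genes (-0.75, 16 of 16 below 0, 10 called, 13 adjusted over the list alone, with Lss at -1.40 and Sqle at -1.22) had one of 0.282. Interferon genes (-0.28, 3 called, 1 higher and 8 lower adjusted over the list alone, with Irf7 at -1.54 and Ifit1 at -1.16) had an adjusted p = 0.354 with an estimated correlation. Adipocyte markers (3.45, 8 called, 12 adjusted over the list alone) and respiratory chain subunits (0.26, 2 called by either adjustment) had one of 0.241. Immediate early genes (0.11, 2 called higher and 1 lower, 7 and 1 adjusted over the list alone) and steroid synthesis genes (0.065, none called) had one of 0.415. The medians of the last pair and of the kidney and liver list changed sign with median centring, to -0.047, -0.095 and -0.016, and that of the kidney and liver list also with a second quantile normalization, to -0.075. Median centring moved the respiratory chain median to 0.097, that of cyclic AMP targets to 0.27, of exocytosis genes to -0.46 and of interferon genes to -0.44.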

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

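The intestine list test, the receptor gene test, the genomic span test and the splits of the arrays were set before their results were seen, while the tests of an array-wide shift, of a germ-free effect whatever the treatment, of dilution, of fewer chromaffin cells and of the hybridization controls were chosen after the result was seen. The reading of the tests of dilution, receptor genes, hybridization controls and the array-wide shift was made stricter after the values were seen, each time toward leaving the question open, and the genes of the test of a germ-free effect were divided into parts after its values were seen.

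Between germ-free and colonized mice the insulin effect differed, by limma's test of the difference, for Gh (4.32), Slc25a20 (1.06), Reg1 (-5.43), Guca2b (-4.52), Muc13 (-3.83), Slc5a1 (-3.20) and Adarb1 (-1.52). Negative control probe sets, which take no part in the comparisons, were higher in germ-free than in colonized arrays by a median of 0.50.

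In the germ-free saline arrays intestinal genes reached levels found in no other group: Guca2b 9.18 to 11.23, Apoa4 9.08 to 11.15 and Reg1 8.33 to 10.37, where the other arrays lay at 5.18 to 6.07, 6.48 to 7.05 and 3.54 to 3.93. A shift of all genes in these arrays would have been removed by quantile normalization if all 12 arrays went through RMA together, which is not given. The median difference of -0.032 from the other 9 arrays shows no such shift in the values used. It decides nothing about a shift before normalization. Of 26 intestine markers (2 of which the colonized arrays also hold above 6.85, and none of which is in another list), 46.2% were higher in all 3 germ-free saline arrays than in every other array, against 1.52% of all genes, so intestinal tissue in these samples may be the source of the pattern. Of the 12 markers higher in all 3, 10 ranked animals 7, 9 and 8 from highest to lowest, an order not set as a test. The share of 46.2% lies between the bounds set for it, 50% or more if so and under 10% if not. Markers such as Cdx2 and Myo1a did not stand out. Cdx2 (4.72 to 5.31 in germ-free saline arrays) lay below their negative controls (5.36 to 5.46), so it decides nothing. Intestinal tissue as the source stays open. An effect of the germ-free state whatever the treatment, the biological alternative, is argued against for the 10 highest genes after saline (germ-free minus colonized 3.89 ± 0.62 (SE) after saline, the value they were chosen for, and 0.14 ± 0.11 after insulin) and stays open for the 26 markers (0.78 ± 0.29 and -0.0028 ± 0.047, a gap of 2.62 standard errors where more than 3 were asked for), as does a germ-free effect present after saline alone.

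In the germ-free insulin arrays chromaffin markers were lower than in germ-free saline arrays. Dilution by other tissue would lower adrenal cortex markers equally, and the cortex median lay 0.55 above the chromaffin median, with an SE of 0.65 over 4 and 9 markers, which is too wide to decide. Fewer chromaffin cells in the dissected piece was taken to lower all members of the chromaffin, exocytosis and receptor lists. Of the 53 members 17.0% lay above 0 (7.14% of the 14 chromaffin markers), between the bounds of 0% and 25%. Members that other cells of the piece also transcribe need not fall, so the bound of 0% could hardly be met. The test therefore decides nothing, and fewer chromaffin cells cannot be told apart from a change in chromaffin cells. Adipocyte markers averaged 8.92 in germ-free saline and 9.99 in germ-free insulin arrays. A lower expression of Gata2, Phox2a and Hand2 after insulin in germ-free mice is the biological alternative and stays open beside them, untested.

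Germ-free and colonized arrays stood apart over all probe sets, with negative controls at 5.30 to 5.54 against 4.70 to 4.83. More unspliced RNA in germ-free samples was taken to raise genes of long genomic span. The correlation of span with the germ-free difference across genes was rho = -0.0716 after saline and -0.0502 after insulin. This argues against it only if the probe sets register unspliced RNA more in longer genes, which was not tested. Genomic DNA would raise the receptor genes of smell and pheromones, and 1412 of them differed by 0.0067 (SE between arrays 0.0168), but at a mean of 4.05 they lie below the negative controls (5.26), so they decide nothing; the labels state a DNase step. The 4 hybridization controls differed by -0.12 between germ-free and colonized arrays, against an SD of 0.13 within them, so a batch of hybridization or scanning may contribute and cannot be told apart from colonization, since no array batch is given in the sources used here. A biological effect of the germ-free state on RNA composition stays open and was not tested.

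Other splits of the same arrays were fitted in the same way. For the insulin effect in colonized mice, the 10 splits are too few for a share under 0.05; 2 of the 10 splits called as many genes, the real one 29 and another 150. That other split set animals 1, 4 and 5 against 2, 3 and 6, whose adipocyte markers were at 5.88 to 6.33 and 8.03 to 10.13, and it points to a structure of the samples. For the insulin effect in germ-free mice (85 real, 0 in the highest other split) and the germ-free difference after saline (1342 and 0) and after insulin (1512 and 0), the real split was the 1 that reached its count, and 10 splits are again too few for a share under 0.05. For the difference of the insulin effects, 7 of 100 splits called as many as the real 7 genes, and the highest called 348, so chance is not excluded for that count; the split with 348 again sets animals 1, 4 and 5 apart from 2, 3 and 6 and points to a structure of the samples. For the mean insulin effect, 1 of 100 splits, the real one, reached 80 genes (highest other 37). That is the lowest share that 100 splits can give, so chance is unlikely there but not excluded. The splits do not separate insulin from uneven tissue between the treatment groups.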

How the results depend on the processing

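Covariates for adipocyte markers and for negative controls, and the score over genes changed in both states, were tests chosen after the data were seen. The number of arrays limits the precision of all counts. Signal over background (area under the curve of positive against negative controls) was 0.910 to 0.924 in colonized and 0.861 to 0.869 in germ-free arrays, and its effect on the counts was not tested. No paired analysis was possible because the animals carry running numbers from 1 to 12 and none is shared between groups. Where a value moved the cause was not tested, unless given.

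Genes called for the insulin effect in colonized mice numbered 29, against 12 with all rows, 49 without dim probe sets, 50 with trend and robust options, 66 with array weights, 73 at an adjusted p under 0.1 and 486 at an unadjusted p under 0.05 with a fold of at least 1.5; limma called 0 with the adrenal cortex covariate, the adipocyte covariate and the compared groups alone (1168, 1616 and 1373 at an unadjusted p under 0.05). In germ-free mice the count was 85, against 48 without dim probe sets, 543 with array weights, 38 with the cortex covariate, 318 with the compared groups alone, 135 at an adjusted p under 0.1 and 449 by fold. For the difference it was 7, against 1 with all rows, 11 after quantile normalization, 148 with array weights, 49 at an adjusted p under 0.1 and 1004 by fold; limma called 0 without dim probe sets and with the cortex and the adipocyte covariate (1210, 958 and 1365 at an unadjusted p under 0.05). For the germ-free difference after saline it was 1342, against 3967 with median centring, 2348 with weights, 175 with the cortex covariate, 157 with the compared groups alone (94 higher and 63 lower) and 2442 at an adjusted p under 0.1. After insulin it was 1512, against 3314 with median centring, 3712 with weights, 42 with the adipocyte covariate and 2508 at an adjusted p under 0.1. The negative control covariate gave 0 for both germ-free differences (968 and 900 at an unadjusted p under 0.05); it follows colonization closely, and the median SE rose from 0.14 to 0.56. For the mean effect the count was 80, against 247 with weights, 167 with the adipocyte covariate, 189 at an adjusted p under 0.1 and 253 by fold.

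Leaving out 1 array leaves a group of 2 and gave 1 to 70 genes for colonized mice: 49, 19 and 45 without colonized saline 1, 2 and 3, 3, 2 and 70 without colonized insulin 4, 5 and 6, 4, 1 and 1 without germ-free saline 7, 8 and 9, and 13, 1 and 10 without germ-free insulin 10, 11 and 12. In germ-free mice it gave 25 to 199, beyond 1.5 times for colonized saline 2 (199), germ-free saline 7 (52) and 9 (30) and germ-free insulin 10 (53), 11 (34) and 12 (25). For the difference it gave 83 and 14 without colonized saline 1 and 2, 14 and 43 without germ-free saline 7 and 8, 3 without germ-free insulin 10, and 1 without colonized insulin 4, 5 or 6, germ-free saline 9 or germ-free insulin 11 or 12. After saline the range was 432 to 1929, beyond 1.5 times for colonized saline 1 (870), germ-free saline 7 (432), 8 (513) and 9 (653) and germ-free insulin 11 (889). After insulin it was 450 to 2841, beyond it for colonized saline 2 (2841), colonized insulin 4 (474) and 5 (696) and germ-free insulin 10 (973), 11 (520) and 12 (450). For the mean effect it was 26 to 131, beyond it for colonized saline 2 (131), colonized insulin 4 (53) and 5 (50), germ-free saline 9 (26) and germ-free insulin 11 (34) and 12 (45). Of 178 named genes and lists called, 16 (without colonized saline 1) to 53 (without germ-free saline 9) lost their call with 1 array less, and none of them reversed.

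Lists called in colonized mice numbered 13, against 3 with an estimated correlation and with fry, 8 with the cortex and 7 with the adipocyte covariate, and 7 (without colonized saline 2) to 16 with 1 array less. In germ-free mice there were 12, against 0 with an estimated correlation and 7 with fry. For the difference there were 15, against 0, 1 with fry, 6 and 7 with the covariates. After saline there were 8, against 0 with an estimated correlation and 4 without dim probe sets, after insulin 13, against 0 and 7 with the adipocyte covariate, and for the mean effect 10, against 3 with an estimated correlation and 3 with fry.

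Directions reversed as follows, with adjusted p and its range over 18 alternatives. With the adipocyte covariate, fibroblast markers in colonized mice (0.293; 1.19e-06 to 0.953), adipocyte markers in germ-free mice (0.849; 4.28e-08 to 0.849), cholesterol synthesis (0.512; 4.61e-05 to 0.512), fibroblast (0.000993; 3.21e-05 to 0.482) and adipocyte markers (0.912; 4.06e-19 to 0.912) for the difference, and adipocyte markers after insulin (0.983; 1.45e-16 to 0.983); the adipocyte list is the covariate itself. With the cortex covariate, cholesterol synthesis (0.307) and fibroblast markers (0.257) for the difference, and respiratory chain subunits after saline (0.792; 0.000516 to 0.792). None of the named genes that reversed was called: Ddc in colonized mice (-0.0023 after quantile normalization; -0.16 without colonized saline 3 and -0.12 without colonized insulin 4, up to 0.11), Npy in germ-free mice (0.030 without germ-free insulin 12; from -0.27), Fos in germ-free mice (0.058 without germ-free saline 8 and 0.0054 without germ-free insulin 10; from -0.14), and for the mean effect Th (-0.015 without colonized saline 2; up to 0.13) and Chga (0.027 and 0.033 without colonized saline 1 and 3, 0.0039 without colonized insulin 6, 0.025 without germ-free insulin 12; from -0.15).

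The difference in response size, 0.64, was 0.035 without dim probe sets and -0.14 over genes changed in both states; leaving out 1 array gave -0.011 (colonized saline 1, exact permutation p = 0.97) to 1.40, with 0.36 (p = 0.095) without colonized saline 3 and 0.14 (p = 0.28) without colonized insulin 6. It was 0.62 to 0.66 with 100 genes, a second quantile normalization or median centring; leaving out cortex and red cell genes removed no gene of the score. The correlation of the insulin effects, 0.107, was 0.0463 without dim probe sets and 0.00432 to 0.150 with 1 array less, and over called genes, 0.532, it was 0.375 to 0.602.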

Other observations

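The lists of liver, pituitary and ganglion markers were written after the first results were seen, and the values here were tests of no hypothesis.

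Liver markers stood at 9.77 in colonized saline animal 2 and at 5.59 and 6.70 in the other colonized saline animals, with Alb at 13.23, 5.61 and 10.53. The germ-free saline arrays held Alb at 11.48 to 12.97, the germ-free insulin arrays at 6.66 to 11.23 and the colonized insulin arrays at 5.86 to 6.32. Markers of sympathetic ganglion neurons reached 9.48 in colonized saline animal 2, the highest value among the 12 arrays. Of the 23 liver markers measured 5, and of the 14 ganglion markers 12, averaged above 6.85 in colonized arrays.

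Gh stood at 10.31 to 12.06, Prl at 7.42 to 9.38, Pomc at 6.29 to 7.04 and Cga at 5.63 to 7.12 in the germ-free insulin arrays, and at 5.17 to 7.81, 4.66 to 5.81, 4.61 to 5.47 and 4.00 to 4.85 in the other 9 arrays. Each of these hormone genes was lowest in animal 10 and highest in animal 12 among the 3 germ-free insulin arrays. Of 11 other pituitary markers 0 were higher in all 3 germ-free insulin arrays than in every other array, against 1.75% of all genes. Their median difference was 0.07. Of these 11, 4 averaged above 6.85 in colonized arrays, where a small addition would hardly show. The markers therefore do not tell whether pituitary RNA was present.

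The first principal component held 35.4% of the variance and the second 23.9%, along which colonized saline animal 2 lay at -57.8. The third held 12.4%.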
